A study of Drosophila melanogaster with 4 samples.

How the data were processed

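The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of HP2 in nuclei of adult fly heads. HP2 is a nonhistone chromatin protein of Drosophila melanogaster that partners with heterochromatin protein HP1. The flies were of the wild-type strain Oregon-R, mixed adults by the labels. Per the labels' protocols, heads were collected from whole adults with sieves, the tissue was homogenized and fixed with formaldehyde, and chromatin was sonicated and precipitated with an antibody (Ab2-90) on protein A beads. There were 4 samples: 2 HP2 ChIP samples and 2 inputs, with replicate numbers taken from the titles. Each input label names the ChIP replicate it served. Nothing in the labels says whether the replicates came from separate fly collections, so the spread between them may be technical.

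Each ChIP replicate had 1 deposited list of enriched regions, called clusters here, and 1 further deposited list was made from the replicate set. The authors described the entries as regions of significant enrichment, per the file headers and columns. Each entry holds a start, an end and 1 score. The authors' score was positive in every entry of the 3 deposited lists, and its scale is not given in the sources used here. It was therefore used to rank, filter and describe clusters and to compare clusters within a list. Differences of scores are in the authors' unit and are not fold changes. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The caller, its threshold and the way the replicates were combined are not given in the sources used here. Coordinates are 1-based on FlyBase r5, per the file headers, which also gave the length of each arm and scaffold. The lists hold no read counts, so the sequencing depth is unknown and no interval that needs it is given. The inputs enter only through the authors' calls, and a value per input library was not analysed here.

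Clusters that ran past the stated end of their scaffold were trimmed to it: 1 in each replicate's list and 2 in the combined list. Bases in clusters were counted once where clusters overlapped. The share of an arm is the number of its bases in clusters over its stated length, unassembled bases included. The long arms are 2L, 2R, 3L, 3R and X. Their proximal part is the 2 Mb at the centromere side of the assembled arm (the right end of 2L, 3L and X, the left end of 2R and 3R), and the rest is called distal. A cluster was placed by its midpoint. A cluster was called shared when at least 50% of its bases lay in clusters of the other replicate. Clusters were matched one by one where the overlap was at least 50% of both.

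Shared bases were tested with a one-sided permutation test: the list of replicate 2 was shifted in a circle along each arm or scaffold of at least 1 Mb, in bins of 100 bp, 100000 times. A second version kept the shifts within windows of 1 Mb. Scores were compared with a two-sided permutation test of the difference of medians (100000 permutations), with Benjamini-Hochberg adjustment over 4 tests. These tests treat positions or clusters of 1 genome as units, which are not independent replicates. Chromosome 4 was compared with the 5 long arms by an exact permutation over 6 arms, which cannot go below p = 0.167. Proximal and distal parts were compared by an exact two-sided sign-flip permutation over the 5 arms, which cannot go below p = 0.0625. Shares of clusters have 95% Wilson intervals, which cover counting error only. Values over both replicates are means with the SD (n = 2). Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

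The tests were checked on simulated data. Lists with the cluster numbers and lengths of both replicates (4700 and 4126 clusters) were placed independently and uniformly along each arm. They passed the threshold of 0.05 in 5 of 100 runs with shifts along arms and in 3 of 100 runs with shifts in windows. Lists that shared 10% of their clusters passed in 20 of 20 runs with either. Uniform placement lacks the crowding of the real lists near the centromere, so these rates do not cover independent lists that share such crowding. All simulated runs used fewer shifts or permutations than the tests of the data. For the score of chromosome 4 against distal clusters, 8 of 100 runs with no shift passed, and 100 of 100 runs with a score shift of 0.2 passed.

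Regions were named by a rule fixed before the data were examined: the 10 longest shared clusters, the 10 longest shared distal clusters and the 10 shared distal clusters of highest score, each taken from the list of replicate 1 with its coordinates. Alternatives were clusters scoring at or above the median of their list, clusters of at least 1 kb, merging of clusters within 1 kb, the combined list, each replicate alone, other proximal sizes and other definitions of overlap. Planned comparisons with genes, with 12 gene lists, with annotation classes and with repeats were not run. The gene table at hand is on Release 6, coordinates were not converted, and a genome sequence was not used here. Regions are therefore given by arm and coordinates, with no gene names.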

Results

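HP2 binding was mapped in adult head nuclei in 2 ChIP replicates, each called by the authors against its own input. Replicate 1 held 4728 clusters covering 14.2 Mb, or 10.1% of the FlyBase r5 assembly without the Uextra scaffold. Replicate 2 held 4163 clusters covering 13.05 Mb, or 9.34%. The authors' combined list was longer, with 7037 clusters over 20.4 Mb (14.6%). Most clusters were short: the median length was 2100 bp in replicate 1 and 2085 bp in replicate 2, while the longest reached 103159 bp and 110614 bp. The shortest measured 1301 bp in both replicates and 1001 bp in the combined list. Uextra, the 29.0 Mb scaffold of unplaced sequence, held 0 clusters in all 3 lists. Read depth is unknown, since the lists hold no counts.

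The first question was where in the genome HP2 was enriched. Chromosome 4, the small autosome known as largely heterochromatic although it carries active genes, stood far above the long arms. Clusters covered 71.7% of it in replicate 1 and 70.8% in replicate 2, a mean of 71.2% ± 0.59 (SD, n = 2). The 5 long arms averaged 8.18% ± 0.97 (SD, n = 2). Chromosome 4 was thus covered 8.77 ± 0.97 times as much (SD, n = 2). Among the long arms, 2R had the highest share, 12.3% ± 1.01 (SD, n = 2), followed by 3L at 8.36% ± 0.72, 2L at 8.16% ± 0.76, X at 6.73% ± 1.42 and 3R at 5.38% ± 0.96. Chromosome 4 ranked first of 6 arms in each list, which gives p = 0.167 in the exact one-sided permutation, the smallest the design allows. Clusters on chromosome 4 were also long, with a median of 4982 bp in replicate 1 against 2075 bp for distal clusters of the long arms, and of 4326 bp against 2051 bp in replicate 2.

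**Figure D1:**
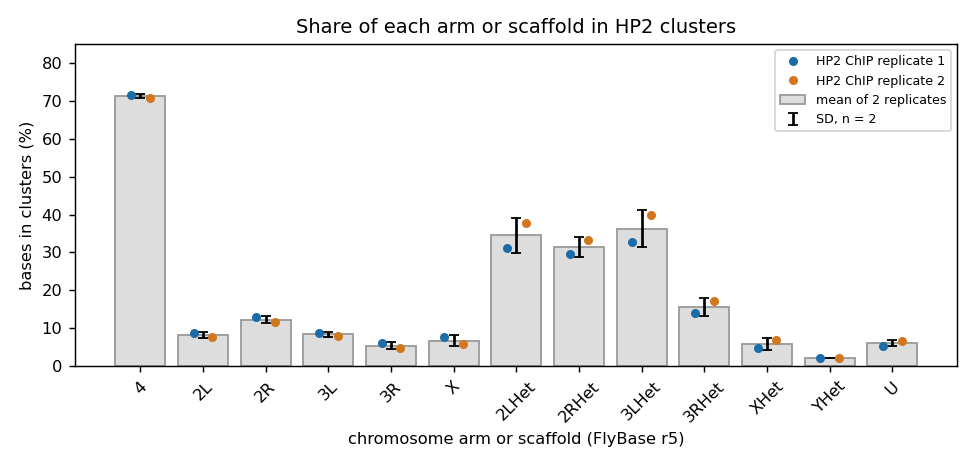
Share of bases in HP2 clusters (%, vertical axis) for each chromosome arm or scaffold (horizontal axis); bars are means of the 2 replicates, error bars the SD (n = 2), points the single replicates. Chromosome 4 stands at 71.2%, 2LHet, 2RHet and 3LHet between 31.5% and 36.3%, and no long arm is above 12.3%.

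Enrichment along chromosome 4 was uneven in the same places in both replicates. Of its 27 full windows of 50 kb, 8 were at least 90% covered in both replicates. Between positions 150001 and 250000, for example, coverage was at least 99.2% in each window and replicate. Coverage was low in 2 windows: that from 400001 to 450000 was 13.3% covered in replicate 1 and 11.1% in replicate 2, and that from 500001 to 550000 was 25.9% and 21.2% covered. The bases called in both replicates made up 91.6% of those called in either. Independent placement would give 55.3% at this coverage, so the value is not comparable with the 60.6% to 78.5% on the long arms, where independent placement would give 2.72% to 6.51%.

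**Figure D2:**
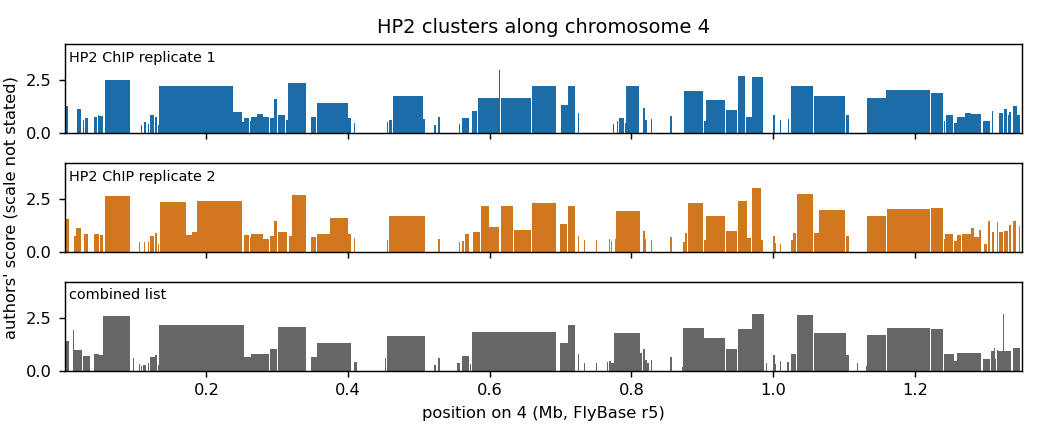
HP2 clusters along chromosome 4 (position in Mb on FlyBase r5, horizontal axis) in replicate 1, replicate 2 and the combined list; the height of each block is the authors' score, whose scale is not stated. Long clusters alternate with sparse stretches, such as the window from 400001 to 450000, at like positions in the 3 lists.

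The next comparison set the centromere-proximal 2 Mb of each long arm, pericentric on the assembled chromosome, against the rest of the arm. Proximal 2R was 64.0% ± 1.23 covered (SD, n = 2) against 6.86% ± 1.24 distally. Proximal 3L was 39.5% ± 3.76 covered against 5.60% ± 1.12, and proximal 2L 35.1% ± 0.71 against 5.60% ± 0.90. On 3R the proximal part reached only 9.27% ± 0.89 against 5.08% ± 0.97. On X it lay lower than the distal part, at 4.56% ± 0.22 against 6.94% ± 1.58. Over the 5 arms the mean difference was 23.0 percentage points in replicate 1 and 26.0 in replicate 2, positive on 4 of 5 arms, with p = 0.125 in each replicate (exact two-sided sign-flip permutation). The mean over both replicates, 24.5 points, depended on the size of the proximal part and fell to 12.2 points with 4 Mb. This exact permutation cannot go below p = 0.0625, so it could not pass 0.05 whatever the data. The difference was larger than the spread between replicates on 2L, 2R, 3L and 3R, though on 3R it was only 4.14 points in replicate 1 and 4.25 in replicate 2, and fell to a mean of 2.16 points when only clusters at or above the median score of their list were kept and 1.61 with a proximal part of 4 Mb. On X it was -3.65 points in replicate 1 and -1.12 in replicate 2, and a mean of -0.83 with the high-scoring clusters.

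The covered stretch ended abruptly on the 3 arms that had one. On 2R, coverage in bins of 250 kb stayed at 71.0% or more in replicate 1 over the first 1.5 Mb from the proximal end, then dropped to 37.6% and to 10.9% in the next bins. On 2L, the bin from 0.75 to 1 Mb was 50.7% covered in replicate 1 and 49.1% in replicate 2, and the bin from 1 to 1.25 Mb was 1.68% and 1.53% covered. Coverage on 2L then rose again in part. The next bins, up to 2 Mb, were 17.0% and 16.9%, 7.37% and 6.70%, and 18.9% and 14.9% covered. On 3L, the bin from 1.25 to 1.5 Mb was 65.3% and 70.4% covered and the next 15.7% and 10.3%.

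**Figure D3:**
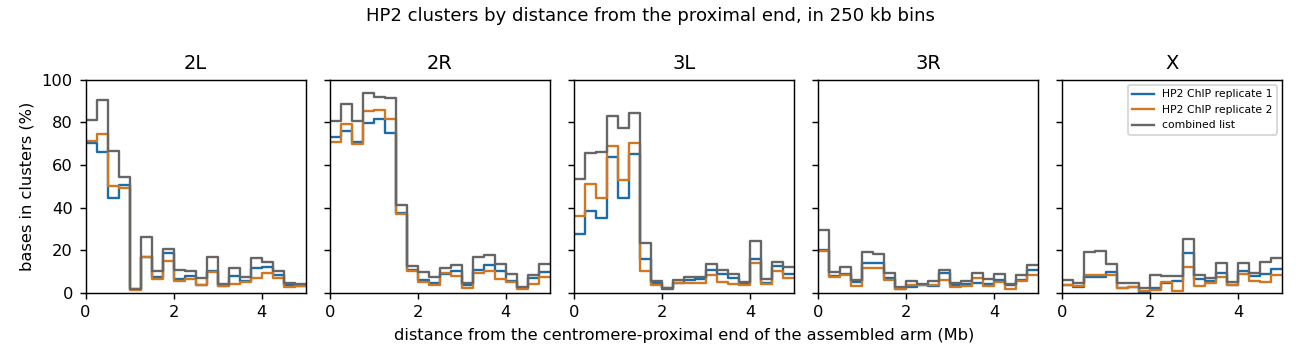
Share of bases in HP2 clusters (%, vertical axis) in 250 kb bins by distance from the centromere-proximal end of each assembled long arm (Mb, horizontal axis), for both replicates and the combined list. Coverage is high over the first 1 Mb of 2L and the first 1.5 Mb of 2R and 3L, while on 3R the first bin reaches 20.2% in replicate 1, 19.6% in replicate 2 and 29.5% in the combined list, and on X no bin of the first 2 Mb exceeds 9.74% in replicate 1, 8.50% in replicate 2 or 19.5% in the combined list.

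The r5 assembly also carries scaffolds of heterochromatin that could not be joined to the arms. Of these, 3LHet was 36.3% ± 4.97 covered (SD, n = 2), 2LHet 34.5% ± 4.69 and 2RHet 31.5% ± 2.57. The share on 3RHet was 15.6% ± 2.29. It was 5.83% ± 1.51 on XHet and 2.15% ± 0.08 on YHet, where 3 clusters were called in replicate 1 and 1 in replicate 2. The unplaced scaffold U was 6.01% ± 0.81 covered. The authors' combined list covered more of each scaffold: 59.6% of 3LHet, 51.8% of 2LHet, 50.2% of 2RHet, 29.2% of 3RHet, 17.7% of XHet, 4.46% of YHet and 15.0% of U. The 6 Het scaffolds and U together were covered 2.04 ± 0.49 times as much as the long arms (SD, n = 2), and the Het scaffolds alone 3.41 ± 0.80 times as much. Gaps in these scaffolds count as uncovered, so the shares are lower bounds for their sequenced part. Among single scaffolds, U, XHet and YHet lay below the mean of the 5 long arms in the replicate means (8.18%). In the combined list U and XHet lay above that of the long arms (11.7%), while YHet stayed below it. No test was run over scaffolds.

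The lists of the 2 replicates coincided far more than chance placement gives. They shared 11.2 Mb, which was 79.0% of the bases of replicate 1, 85.7% of those of replicate 2 and 69.8% of the bases in either. On the arms and scaffolds of at least 1 Mb, 11.05 Mb were shared, against 2.26 Mb on average after shifting along arms (p = 1e-05, one-sided permutation test, the smallest that 100000 shifts can give). Shifts within 1 Mb windows, which keep the crowding near the centromere, gave 3.59 Mb on average and at most 4.14 Mb (p = 1e-05, same permutation test). On the distal arms alone, 5.17 Mb were shared against 0.385 Mb after shifting (p = 1e-05, permutation test). Among 2358 matched distal clusters, the starts differed by a median of 57 bp and the ends by 59 bp. The offsets were larger for matched proximal clusters (145 and 154 bp), on chromosome 4 (169.5 and 189.5 bp) and on the scaffolds (247.5 and 243 bp). Matching required 50% reciprocal overlap, which itself limits these offsets. Across all 3257 matched clusters, the authors' scores of the 2 replicates had a Spearman rho of 0.86. That is a relation across clusters, which are not independent replicates.

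Sharing differed between parts of the genome and, mainly in replicate 1, with the score. On the distal arms, 93.4% of the 2581 clusters of replicate 2 were shared (95% Wilson interval 92.3% to 94.3%), but only 72.1% of the 3291 clusters of replicate 1 (70.6% to 73.6%). On the Het and U scaffolds the order was the other way round. There 57.3% of the 900 clusters of replicate 2 were shared (54.1% to 60.5%), and 74.2% of the 770 clusters of replicate 1 (70.9% to 77.1%). The shared clusters themselves were closer in number. There were 2410 in replicate 2 and 2374 in replicate 1 on the distal arms, and 516 and 571 on the scaffolds. These contrasts between replicates thus largely followed the number of clusters that each list held. Chromosome 4 gave 90.7% (82.7% to 95.2%) in replicate 1 and 90.6% (83.1% to 94.99%) in replicate 2. With 71.7% and 70.8% of chromosome 4 in clusters, many would be shared by placement alone. No chance level was computed for shared clusters, so its value is not comparable with those of the other parts. Among distal clusters of replicate 1, the fifth with the lowest scores was shared at 42.6% (38.9% to 46.4%), and the fifth with the highest at 99.8% (99.1% to 99.97%), or 657 of 658. In replicate 2 the corresponding groups spanned less: the lowest was shared at 89.2% (86.2% to 91.6%), the next at 88.4% (85.3% to 90.9%) and the highest at 99.6% (98.6% to 99.9%). In the combined list, 2209 of the 7037 clusters (31.4%) touched no cluster of either replicate. Their median score was 0.435, against 0.575 for the others. The gap was small on the Het and U scaffolds, where 840 of 1711 combined clusters (49.1%) touched neither replicate, with medians of 0.600 against 0.640. On the distal arms 25.8% touched neither, with medians of 0.365 against 0.530. The combined list contained 99.9996% of the bases shared by both replicates.

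Clusters also scored higher in the heterochromatic parts. The median score on chromosome 4 was 0.836 in replicate 1 and 0.858 in replicate 2, and that of distal clusters 0.659 and 0.646. The difference was 0.18 in replicate 1 (adjusted p = 0.0011, permutation test with Benjamini-Hochberg adjustment) and 0.21 in replicate 2 (adjusted p = 5.3e-05). Proximal clusters had medians of 0.761 and 0.775, which exceeded the distal medians by 0.10 and 0.13 (adjusted p = 2e-05 in both, same permutation test). Longer clusters had higher scores (Spearman rho 0.65 across clusters in replicate 1 and 0.63 in replicate 2), and clusters of chromosome 4 and the proximal parts were longer. No comparison at equal length was run, so the score differences cannot be told apart from this difference in length.

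Of the 10 longest shared clusters, 6 lay on chromosome 4, 2 on 2R and 1 each on 3L and 2RHet. The longest spanned 103159 bp of chromosome 4, from 133719 to 236877, with a score of 2.21 in replicate 1. Replicate 2 covered 99.5% of it with 4 clusters. The second spanned 93777 bp of proximal 2R, from 947022 to 1040798, with a score of 2.32, and was 99.4% covered in replicate 2. The third, also on proximal 2R, ran from 374686 to 443886 and scored 2.48. On 3L the cluster from 23670264 to 23726909 scored 1.81, and on 2RHet that from 441362 to 491040 scored 2.00. Replicate 2 covered at least 97.2% of each of the 10.

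Distal clusters of the long arms were much shorter, yet some scored higher than any of these 10, which were chosen by length. The top-scoring cluster of each replicate was not distal. The highest score was 4.67 in replicate 1 and 3.94 in replicate 2, against 3.70 and 3.88 among distal clusters. The longest shared one ran from 10225454 to 10240596 on 2L (15143 bp), with a score of 3.44 in replicate 1 and 3.56 in replicate 2. The next lay on 2R, from 19939956 to 19952489 (12534 bp), and scored 3.21 and 3.05. A cluster near the distal end of 3L, from 51308 to 62419, scored 1.39 and 1.27. On 3R the longest ran from 4875266 to 4884778 with scores of 1.02 and 0.888, and on X from 4823538 to 4831918 with 1.00 and 0.957. The highest distal score belonged to a cluster of 3601 bp on 2L, from 10421206 to 10424806, with 3.70 in replicate 1 and 3.88 in replicate 2. A cluster of 4086 bp on 3R, from 2904984 to 2909069, scored 3.55 and 3.58. On X the highest was that from 15826584 to 15829617, with 3.08 and 3.43. Of the 10 highest-scoring shared distal clusters 6 lay on 2L, as did 4 of the 10 longest.

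**Figure D4:**
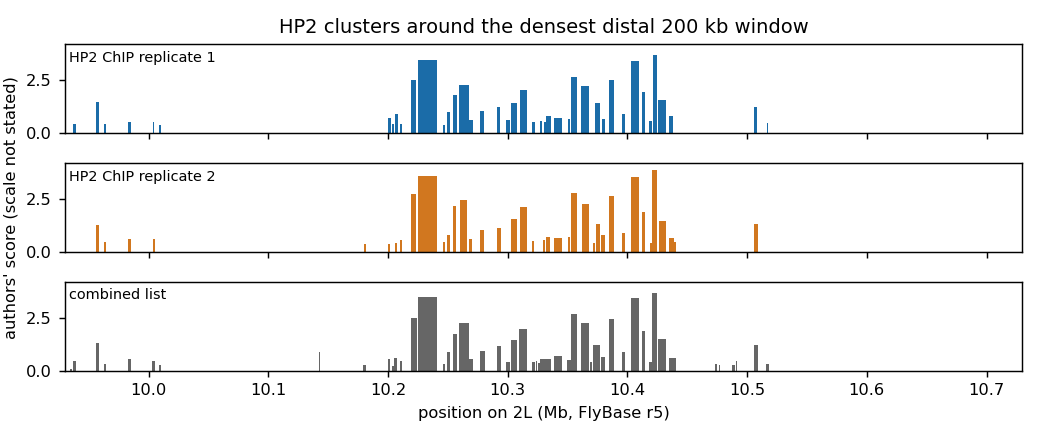
HP2 clusters around the distal 2L clusters of high score (position in Mb on FlyBase r5, horizontal axis) in replicate 1, replicate 2 and the combined list; the height of each block is the authors' score, whose scale is not stated. The cluster from 10225454 to 10240596 (score 3.44 in replicate 1) and that from 10421206 to 10424806 (3.70) lie near the 2 ends of a crowded stretch that the 3 lists share.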

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

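The alternatives below were fixed before the data were examined, except leaving out X or U, which was chosen after seeing the data. Chromosome 4, pooled scaffold and proximal contrasts never changed sign, but those of U and XHet did. With only clusters at or above the median score of their list, shares fell by over 1.5 times on 3R (5.38% to 2.56%), 3L (8.36% to 4.76%), X (6.73% to 4.02%) and 2L (8.16% to 5.16%), so that 3L then ranked below 2L, and 3LHet (27.3%) below 2LHet (32.2%). Both score differences stayed past their thresholds in the combined list, the only setting run for them that changes the clusters used. Each replicate alone only restates the main result, which was given per replicate. The excess of shared bases stayed past its threshold with high-scoring clusters (those at or above the median score of their list), merged clusters, the distal arms, window shifts and without U: shared bases ranged from 66.7% to 70.9% of those in either replicate, all at p = 1e-05 in the permutation test. Covered length, a mean of 13.6 Mb per replicate, became 9.17 Mb with high-scoring clusters and 20.4 Mb in the combined list. The number of clusters, counting those that touch as 1, fell from a mean of 4445 to 2223 with high-scoring clusters and was 7034 in the combined list. The ratio of chromosome 4 to the long arms, 8.77, became 13.03 with high-scoring clusters, 6.66 in the combined list and 12.1 against the long arms without their proximal 2 Mb. The mean proximal minus distal difference of 24.5 percentage points became 21.8 with high-scoring clusters, 30.2 in the combined list, 32.5 with a proximal part of 1 Mb, 12.2 with 4 Mb and 31.2 without X. The ratio of the Het scaffolds and U to the long arms became 2.71 with high-scoring clusters, 2.54 in the combined list and 3.41 without U. The larger proximal part and U brought in sequence of lower coverage. Coverage dropped beyond the covered stretch of 2L, 2R and 3L, and U was 6.01% covered against 27.0% for the Het scaffolds. For the combined list and the high-scoring clusters the cause was not tested. Requiring at least 1 kb removed no cluster, so that setting tests nothing. From 1 replicate alone, the chromosome 4 ratio was 8.08 or 9.45, the proximal difference 23.0 or 26.0 points and the scaffold ratio 1.69 or 2.38. Of the 28 named regions, 1 (2L, from 10338432 to 10345209) was lost with high-scoring clusters only; under the other alternatives at least 81.4% of each stayed covered. No paired analysis was possible because no value per input library was analysed here and the replicates form 1 group; shared bases need both replicates, so neither could be left out there. The gene, gene list, annotation and repeat alternatives were not run, for want of an annotation on r5. Unknown depth limits the calls: a base outside the clusters was not called enriched at the authors' threshold, which does not show that HP2 is absent.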

Other observations

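Besides the pericentric regions, the arms held local crowds of clusters. Over sliding 200 kb windows of the distal arms, the median window was 6.14% covered in replicate 1 and 4.53% in replicate 2. The densest window lay on 2L, from 10230001 to 10430000, at 55.7% and 52.3%, with 26 clusters in replicate 1 and 25 in replicate 2. Next, by the mean of both replicates, came 2R from 19830001 to 20030000, at 31.4% and 27.8%, and X from 15640001 to 15840000, at 32.6% and 26.4%. Their order was the other way round in replicate 1 and in the combined list, with 36.1% on 2R and 40.4% on X in the latter. Of the telomeric ends, the outermost 50 kb of X was 26.9% and 25.7% covered, that of 3R 10.4% and 9.76%, that of 2L 9.22% and 9.01%, that of 2R 0% and 2.93%, and that of 3L 0% in both. The 3L value depends on that limit, since a shared cluster of 11112 bp starts at 51308, and the combined list covered 2.03% of the outermost 50 kb there. Of the other ends, the combined list covered 44.4% on X, 10.5% on 3R, 9.33% on 2L and 3.21% on 2R. Distal clusters on X scored higher than those on the autosomal arms, with medians of 0.732 against 0.626 in replicate 1 (p = 1e-05, two-sided permutation test over clusters) and 0.705 against 0.621 in replicate 2 (p = 3e-05). The lower tail differed more, with 5th percentiles of 0.456 against 0.343 and 0.461 against 0.333, than the 95th percentiles, at 1.65 against 1.61 and 1.65 against 1.57. Fewer X clusters were shared, 67.4% against 73.5% in replicate 1 and 90.9% against 94.0% in replicate 2. The authors' threshold is unknown, so the higher medians do not show stronger HP2 binding on X. These windows, ends and X values were chosen after seeing the data, and so was the 2L block tested below. Of the tests below, only that on low-scoring calls had its criterion written beforehand, for a block already picked from the data.

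The 2L block was weighed against chance and against weak calls. In 1000 random placements of the distal clusters of each replicate, 0 reached the density seen. The densest placed window was 27.1% covered in replicate 1 and 24.6% in replicate 2, which argues against chance crowding under uniform placement. The next windows, on 2R (31.4% and 27.8%) and X (32.6% and 26.4%), exceeded these values too. Crowding beyond uniform placement was therefore not particular to the 2L block. With only clusters at or above the median score of their list, 76.4% of the block's covered bases remained in replicate 1 and 83.5% in replicate 2, against 51.4% and 48.8% of the other distal bases, which argues against low-scoring calls near the threshold as the whole cause. Longer clusters score higher, so this filter also favours them. Each replicate was called against its own input. The copy number and mappability of this stretch in the flies used were not analysed here, and no test here addresses what the block is.

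The replicates differed in which compartment they covered more. Replicate 2 covered 0.843 times the length of replicate 1 on the long arms, but 1.18 times on the Het scaffolds, with 1.12 on 2RHet, 1.21 on 2LHet, 1.21 on 3LHet and 1.23 on 3RHet. On chromosome 4 the ratio was 0.988. The distal parts of all 5 long arms were covered less in replicate 2, as on 2R with 5.98% against 7.74%. The proximal parts were covered more in replicate 2 on 2L (35.6% against 34.6%), 2R (64.9% against 63.2%), 3L (42.2% against 36.9%) and X (4.71% against 4.40%), but less on 3R (8.65% against 9.90%). No explanation for this difference was tested.

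Proximal X and 3R lacked the dense coverage of 2L, 2R and 3L. A candidate explanation is weak enrichment missed in single replicates. The combined list, which covered more bases, reached 13.4% of proximal 3R and 9.31% of proximal X, against 43.9% or more on the other arms. Its added calls thus did not close the gap. Enrichment too weak for that list as well cannot be excluded, since its threshold and the way it was made are unknown. The replicate means were 9.27% on proximal 3R and 4.56% on proximal X, so coverage rose there in the combined list. It rose elsewhere too: proximal 2R went from 64.0% to 72.7%, 3L from 39.5% to 57.3% and 2L from 35.1% to 43.9%. Distal 3R rose from 5.08% to 7.65% and distal X from 6.94% to 11.4%. The rise was thus not particular to proximal X and 3R, and whether part of the gap is weak enrichment stays open. Another candidate explanation is that the assembled arms of X and 3R end short of heterochromatin placed on their Het scaffolds. XHet and 3RHet were covered to at most 17.3% in a replicate, below the 29.7% or more of 2LHet, 2RHet and 3LHet. This cannot be told apart from lower mappability or more gaps in XHet and 3RHet, since neither was measured here. A difference between chromosomes in HP2 binding itself also stays open and untested.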
